A study of Homo sapiens with 7 samples.

How the data were processed

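MicroRNAs were measured in 7 HCT116 samples, 5 treated with CPT and 2 with DMSO, on arrays of 1 slide scanned once, so that slide and scan date could not act as batches. Total RNA was labelled with Cy3 by a core facility, per the labels. The scanner files hold the intensity of each spot, and per the file headers they were made with Agilent Feature Extraction 10.7.1.1. The processed signal used here is background-subtracted and not scaled between arrays, per the file headers. The flags for detection and outliers are part of the same deposited files. The deposited table of values holds log2 values. On all 7 arrays each of its 939 entries equals log2 of the total gene signal where the entry was detected and 0 elsewhere, within 1e-06, with no scaling between arrays. Of these, 3 carry another name in the table and were matched by hand, and their equal values bore this out. Its column medians were 9.21 for DMSO 4 h and 0 for the other arrays. Scale, centring and direction of that table are thereby known.

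From the scanner files, control spots and outlier-flagged spots (8.83% of spots) were left out. The processed signals of each probe's spots were averaged, and the means of the 1 to 4 probes of a miRNA were summed. Each array was divided by its 75th percentile over the 299 human miRNAs detected on all arrays, since most entries were not. These percentiles ran from 2898 on CPT 2 h to 12920 on DMSO 4 h. A floor was then set at the lowest signal among detected miRNAs of that array, and log2 was taken. No spot was saturated (0 spots). A human miRNA was tested if detected on all arrays of at least 1 group, which gave 413. All 413 were detected on both DMSO arrays, so that none entered through a CPT group alone. This filter favours differences below DMSO. Over the 299 miRNAs detected on all arrays, the median difference from DMSO was -0.01 in CPT late and -0.14 in CPT early. Over the 413 it was -0.21 and -0.47. In 41 of 395 miRNAs with 2 or more usable probes, probes differed in sign between CPT late and DMSO. At-least folds were given only for entries that were neither detected nor well above background on any array of a group. Precision is limited by the number of arrays.

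The tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with 1 mean per group over all 7 arrays, Benjamini-Hochberg adjustment and a threshold of 0.05. Residual degrees of freedom were 4 and prior degrees of freedom 5.75. Lists of miRNAs were tested with camera, with preset and estimated correlation, and with fry, where 3 or more members were tested. Of these lists 19 qualified, and the viral entries were kept apart as a background set. The time-matched pairs were described without a test of single miRNAs. Their list medians were set against random lists matched on expression, which with 1 array per side takes no account of the spread between arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

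Most miRNAs named in the text came from a rule fixed before the data were examined. The groups, lists and most alternatives were fixed then too. Others, such as miR-548d-5p, miR-20a*, miR-513a-3p, miR-223 and miR-451, were named after results were seen. The rule takes for each comparison the 12 largest changes each way that passed, filled to 8 with the smallest unadjusted p, miR-142-3p, miR-142-5p, the miR-34 family, miR-21 and miR-210, up to 4 members of each list, the 5 largest differences each way in a pair, and up to 6 at-least folds. Not every miRNA so chosen is printed.

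The fit was tested on simulated data in which 40 of 413 miRNAs were changed. For CPT late against DMSO it recovered 90.2% of changes of 8-fold, 27.2% of 4-fold and 0.75% of 2-fold. For CPT early against DMSO it recovered 94.8%, 39.8% and 0.625%, and for CPT late against CPT early 93.9%, 40.8% and 0.5%. The simulation used equal spread within groups and independent noise for each miRNA. In the data, estimated correlations within lists ran from -0.09 (miR-15-16 family) to 0.98 (let-7 family). The recovery is therefore not the power of the real comparisons.

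Alternatives covered the summary of probes, the scaling, the background, the filter, the side of the slide as a block, the variance model, array weights, the deposited log2 table, leaving out each array, and time as a term. The normexp alternative used the median spot signal, because the files used here hold that and no mean signal. Names are those of the array's design. The file headers give the build hg18 and the gene table used here is of GRCh38, so that only the order of neighbouring genes was taken from it and no coordinates are given.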

Results

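HCT116 cells, an established human colon carcinoma line with wild-type p53, were treated with camptothecin (CPT), which traps topoisomerase I on DNA, or with DMSO, its solvent. MicroRNAs (miRNAs) in total RNA were measured on 1-colour Agilent arrays, 1 array per condition. CPT arrays were made at 1, 2, 4, 15 and 20 h (10 µM) and DMSO arrays at 4 and 20 h (0.1%). The 7 arrays were placed in 3 groups from their labels, which were DMSO (2 arrays), CPT early (1, 2 and 4 h, 3 arrays) and CPT late (15 and 20 h, 2 arrays). Since the arrays of a group are different time points of 1 series, and nothing in the labels says that they came from separate cultures, p-values measure only the spread between these arrays, and their number limits the precision.

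Each array carried 851 human and 88 viral miRNA entries. The DMSO 4 h array stood apart. It had 691 human entries detected, against 413 on DMSO 20 h and 320 to 430 on the CPT arrays. It also had 65 viral entries detected, against 17 to 26 on the 6 other arrays, although viral miRNAs have no gene in uninfected cells. Relative to the let-7 family, abundant epithelial miRNAs, the mean log2 signal of the 17 viral entries detected on all arrays was -1.17 on DMSO 4 h and -3.19 on DMSO 20 h. On the CPT arrays it was -2.54 at 1 h, -4.41 at 2 h, -3.95 at 4 h, -2.70 at 15 h and -3.31 at 20 h. Values below are log2 signals scaled to each array's 75th percentile. The 413 human miRNAs tested were all detected on both DMSO arrays, which favours differences below DMSO.

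**Figure D1:**
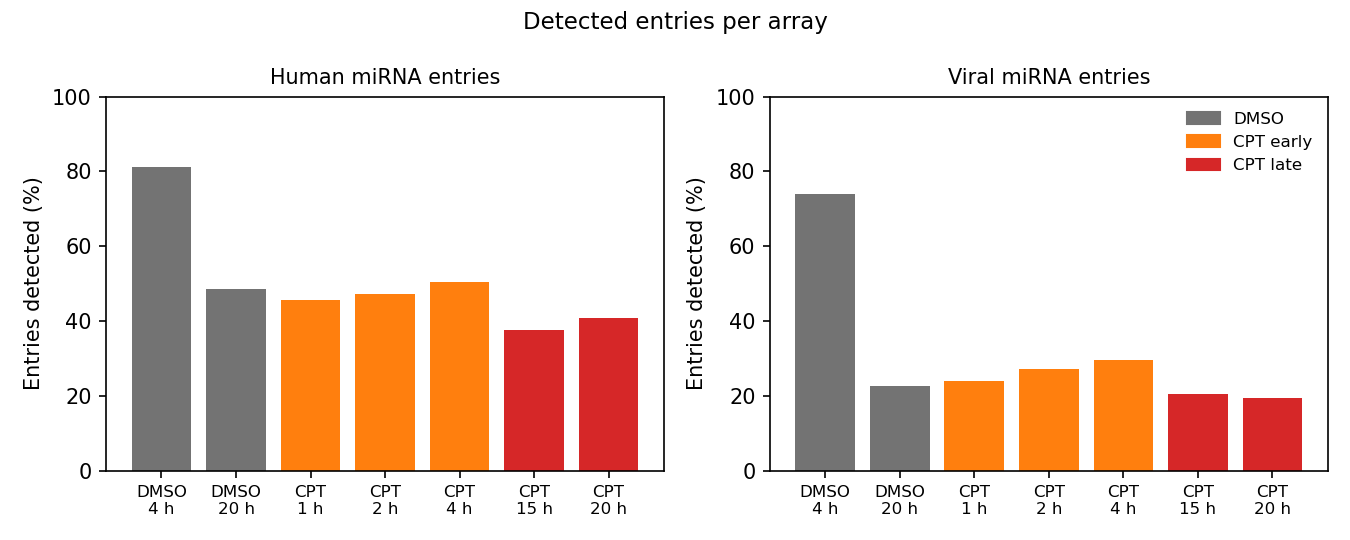
Percent of the 851 human (left) and 88 viral (right) miRNA entries detected on each array, coloured by group. DMSO 4 h reached 81.2% of the human and 73.9% of the viral entries, and the 6 other arrays 37.6% to 50.5% and 19.3% to 29.5%.

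The comparison of CPT late with DMSO asked which miRNAs differ after 15 to 20 h of topoisomerase I inhibition. The series title names miR-142-3p, a miRNA abundant in blood-forming cells. It was at -2.42 ± 0.63 (SD, n = 2) in CPT late and -5.94 ± 0.76 (SD, n = 2) in DMSO, a mean difference of 3.52 ± 0.69 (SE) or 11.5-fold, with a limma adjusted p of 0.199, which was 0.734 with each array's own signal in place of the floor. It was above both DMSO arrays on both late arrays, with unscaled signals of 715 and 825 against 145 and 153. The other arm of its hairpin, miR-142-5p, was detected only on DMSO 4 h and was not tested. No miRNA passed an adjusted p of 0.05 by limma, and 13 of 413 had an unadjusted p under 0.05 (5 higher and 8 lower), where chance gives 20.7.

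The next smallest p-values above DMSO belonged to miR-1274b, an entry that matches a tRNA fragment, at 2.99-fold, miR-22 at 2.83-fold, miR-22* at 2.87-fold and miR-191. The last was detected on 1 of the 2 late arrays and set to the floor at 15 h. Its 3.04-fold became 1.83-fold with its own undetected signal there, which gives no exact fold. The values for miR-132, miR-1915 and miR-183 were 2.61-fold, 2.18-fold and 2.28-fold. On the lower side, miR-513b was 4.34-fold lower (log2 difference -2.12 ± 0.57 SE, adjusted p 0.568), miR-513c 3.44-fold and miR-513a-5p 2.71-fold, though miR-513c was detected on 1 of the 2 late arrays and lay on the other side with normexp background correction (0.21). The minor-arm entries miR-29b-1* and miR-141* were 2.85-fold and 2.49-fold lower, the latter detected on 1 late array. miR-100* and miR-15b* were detected on both DMSO arrays and not above background on either late array, so that their folds are bounds. miR-100* was at least 5.63-fold and miR-15b* at least 3.88-fold higher in DMSO. The same held for miR-1284 (at least 3.90-fold), miR-181c* (at least 3.61-fold) and miR-194* (at least 3.43-fold), with adjusted p of 0.382 for miR-100* and 0.746 for the others. Except for miR-100* these bounds rest on DMSO 4 h, and without it they were 2.01 for miR-15b*, 1.65 for miR-1284, 1.51 for miR-181c* and 1.16 for miR-194*. With normexp the differences of miR-100* (0.20), miR-15b* (0.56), miR-194* (0.62) and miR-141* (0.74) turned too, as did that of miR-191 with total gene signal (-1.01) and that of miR-1915 without scaling (-0.03). A bound sets the bright group's mean against the dim group's own signal or the lowest signal well above background, whichever is higher on each array.

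**Figure D2:**
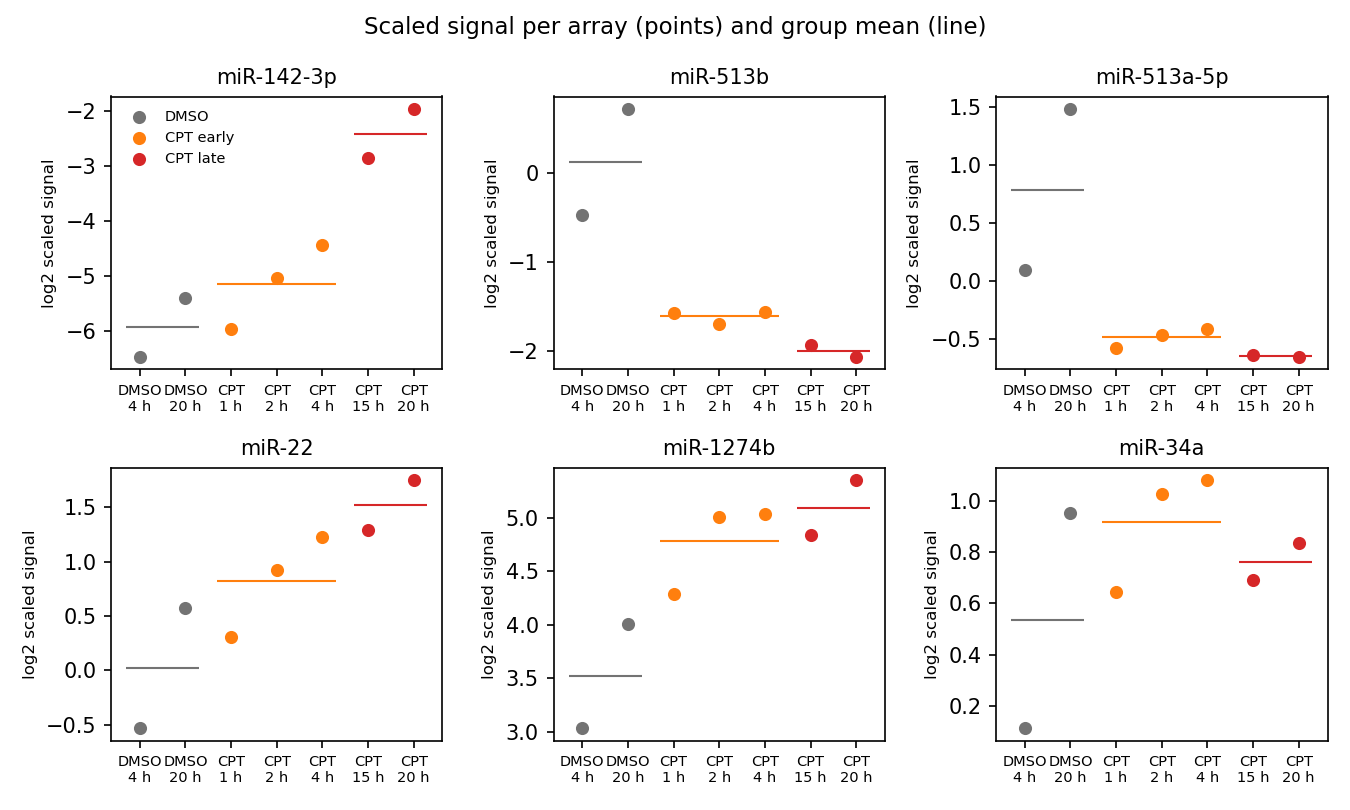
Scaled log2 signal of 6 miRNAs on each array (points) with the group mean (line), coloured by group. miR-142-3p averaged -2.42 in CPT late against -5.94 in DMSO, and miR-513b averaged -1.99 in CPT late and -1.61 in CPT early against 0.12 in DMSO. The miR-142-3p point at 1 h is that array's floor.

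Among the 19 lists with 3 or more tested members, 5 were called by camera in CPT late against DMSO with its preset correlation of 0.01. None of the 5 calls held with an estimated correlation, where each had adjusted p = 0.734, and none was made by fry, with adjusted p 0.663. The adjusted p-values that follow are those of the preset correlation. All 9 members of the let-7 family lay above DMSO with a median of 0.54 (adjusted p 0.0285), which without scaling became -0.61, among them let-7i at 1.55-fold and let-7a at 1.55-fold. The list of entries matching fragments of other RNAs had 7 of 9 above, with a median of 0.95 (adjusted p 0.00797), led by miR-1274b, miR-720 (2.29-fold) and miR-1260 (2.11-fold). Of the colon epithelial miRNAs, 9 of 11 lay above, with miR-31 at 1.74-fold, and of the stress miRNAs 11 of 13, with miR-183 and miR-96 (1.96-fold), each list with an adjusted p of 0.0285. Of the 84 tested star strands, the minor arms of miRNA hairpins, 71 lay below DMSO with a median of -0.53 (adjusted p 0.000504), which with normexp became 0.42. Without scaling, let-7a, let-7i, miR-1260, miR-31 and miR-96 lay below DMSO, let-7a also without DMSO 4 h (-0.06). Without scaling the medians of the other 4 lists were below 0 too, while the median of all tested miRNAs, -0.21 as scaled, was -1.36. Without DMSO 4 h camera called 0 lists, and without CPT 20 h it called 1. All 84 star strands were detected on both DMSO arrays but only 53 on all arrays, a filter that favours values below DMSO. Those 53 followed the viral signal, with a median slope on it of 1.03, both taken relative to let-7. The let-7 median slope of -0.11 is held near 0 by that scaling and shows nothing. The median slopes were -0.09 for the fragments of other RNAs, -0.09 for the colon epithelial miRNAs and -0.06 for the stress miRNAs. Leaving out the scaling moves all miRNAs of an array alike and so cannot test a list against the others. With normexp the let-7 and stress medians moved below that of all tested miRNAs, with differences from it of -0.15 and -0.09. The other 14 lists had adjusted p from 0.0532 (miR-17-92 clusters) to 0.998.

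The p53-responsive list had 12 of 19 members above DMSO and 7 below, with a median of 0.29 and a camera adjusted p of 0.248. Of the miR-34 family, direct p53 targets, miR-34a was at 1.17-fold, miR-34b at 1.07-fold, miR-34b* at 0.97-fold and miR-34a*, detected on 1 late array, at 0.65-fold of DMSO, with adjusted p from 0.746 to 0.961, while miR-34c-3p and miR-34c-5p were detected only on DMSO 4 h. miR-21, the brightest of the fixed miRNAs, was at 1.61-fold (adjusted p 0.746), and miR-210, the hypoxia miRNA, differed by 0.13 on the log2 scale (adjusted p 0.907). The direction of each of these miR-34 entries, miR-21 and miR-210 turned under 1 or more alternatives. In each list, 0 members passed when adjusted over the list alone.

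The comparison of CPT early with DMSO covered the first 4 h. miR-100* was 6.36-fold lower (-2.67 ± 0.55 SE, adjusted p 0.277) and was detected on 2 of the 3 early arrays. miR-513b was 3.32-fold lower, with a mean of -1.61 ± 0.07 (SD, n = 3) against 0.12 ± 0.84 (SD, n = 2), and miR-513c was 2.36-fold lower. miR-148a*, miR-30d* and miR-491-3p were 3.61-fold, 4.21-fold and 3.36-fold lower, miR-30d* being detected on 2 early arrays. The signals of miR-148a* and miR-491-3p followed the viral signal, with slopes on it of 1.165 and 1.235. The direction turned with normexp for miR-30d* (0.09) and miR-513c (0.06), and with total gene signal for miR-148a* (0.34). On the higher side stood miR-1274b (2.40-fold), miR-720 (2.14-fold), miR-1274a (2.09-fold) and miR-1260 (1.89-fold). Without scaling all 4 were lower (-0.04, -0.20, -0.24 and -0.38). Leaving out the scaling moves all miRNAs of an array alike (median -1.77), and so decides nothing about these 4. A fit over entries not following the viral signal, chosen after seeing the data, called only miR-1274b (0.75, limma adjusted p 0.0186). miR-142-3p was undetected at 1 h, so that its difference of 0.79 ± 0.63 SE (adjusted p 0.443) depends on the floor set there, and with the array's own signal it was 0.04. Without scaling it was -0.51, and with the viral covariate -0.10. At-least folds, in favour of DMSO, were 4.66 for miR-222*, 4.54 for miR-548m and 2.62 for miR-597, each with an adjusted p of 0.356. These too rest on DMSO 4 h, and without it they were 2.48 for miR-222* and 1.89 for miR-548m, with no bound left for miR-597. The difference of miR-222* turned with normexp (0.61). By limma 0 miRNAs passed, and 33 had an unadjusted p under 0.05, of which 32 were lower. Since every tested miRNA was detected on both DMSO arrays, the filter itself favours this side. Without the 1 h array, 71 passed, all lower. That array had more viral signal (-2.54, relative to let-7) than those at 2 h (-4.41) and 4 h (-3.95). Those of the 71 that were detected on all arrays followed the viral signal, with slopes from 1.04 (miR-548d-5p) to 1.70 (miR-15a*). Their drop cannot be told apart from that signal, and the cause was not tested further.

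In CPT early, camera called 7 lists, and all of these calls were lost with an estimated correlation (adjusted p = 0.544 for each). Without DMSO 4 h, 2 were called. The let-7 family had 9 of 9 members above DMSO (median 0.64, adjusted p 0.00209), the miR-17-92 clusters, which promote proliferation, 12 of 14 (median 0.55, adjusted p 0.00308), and the fragments of other RNAs 8 of 9 (adjusted p 0.000569). Colon epithelial miRNAs had 8 of 11 above (adjusted p 0.0432), although miR-192 and miR-215, both intestinal, were 2.66-fold and 2.13-fold lower, the latter turning with normexp (0.29). Both of these followed the viral signal, with slopes on it of 1.15 and 1.12. The stress list had 10 of 13 above (adjusted p 0.0155) and the miRNAs in introns of long host genes 15 of 21 (adjusted p 0.0221). Of the star strands, 68 of 84 lay below (median -1.01, adjusted p 0.000569), against a median of -0.47 over all tested miRNAs. Without scaling the medians of all 7 lists were below 0, and with normexp that of the star strands was 0.21. The median of all tested miRNAs moved as well, to -1.77 and 0.35. Relative to that median, normexp brought all 7 lists closer to 0. The let-7 family went from 1.11 to 0.04, the miR-17-92 clusters from 1.02 to 0.06 and the star strands from -0.54 to -0.14. The miRNAs in introns of long host genes went from 0.82 to 0.29. miR-34a was at 1.30-fold, miR-34b at 0.66-fold and miR-21 at 1.70-fold of DMSO, with adjusted p of 0.558, 0.448 and 0.416, and each turned under 1 or more alternatives.

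CPT late was compared with CPT early without use of DMSO values, though the DMSO arrays entered the shared spread. miR-142-3p was higher late by 2.74 ± 0.63 SE (limma adjusted p 0.618) with the undetected 1 h array at its floor, which is 6.66-fold. With that array's own signal it was 11.1-fold, but an undetected signal gives no exact fold. miR-630, linked to DNA damage, was at 3.24-fold, miR-148a* at 2.83-fold, miR-224 at 2.38-fold and miR-1181 at 2.30-fold. Of these, miR-630 and miR-1181 were detected on 1 of the 2 late and 2 of the 3 early arrays. miR-148a* turned with total gene signal (-1.37) and miR-1181 with the deposited table (-0.42). The signals of miR-148a* and miR-224 followed the viral signal, with slopes on it of 1.165 and 0.908. Relative to let-7, that signal was higher at 15 h (-2.70) and 20 h (-3.31) than at 2 h (-4.41) and 4 h (-3.95), but not than at 1 h (-2.54). With the viral covariate the log2 difference of miR-148a* was 1.08. The lower values were closer to 1, with miR-1246 at 1.85-fold, miR-892b at 1.59-fold and miR-583 at 1.54-fold lower, the last pair detected on 1 late array each and turned with normexp (0.14 and 0.18). By limma 0 miRNAs passed and 5 had an unadjusted p under 0.05, all higher. Camera called 0 of 19 lists, but 4 without CPT 1 h or without CPT 20 h, and 2 without either DMSO array. The smallest list p-values were those of the miRNAs in introns of long host genes, with 13 of 21 lower, and of the miR-17-92 clusters, with 11 of 14 lower (adjusted p 0.066 each).

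The time-matched pairs hold 1 array on each side and have no replicate check. Between CPT 20 h and DMSO 20 h, whose viral signals were close, miR-142-3p ranked first of the 344 miRNAs detected on both, at 10.8-fold. It was followed by miR-630 (4.07-fold), miR-638 (2.96-fold), miR-132 (2.75-fold) and miR-194 (2.70-fold). The lowest values were miR-513b at 6.87-fold, miR-513a-5p at 4.40-fold, miR-513c at 3.16-fold, miR-494 at 2.87-fold and miR-141* at 2.85-fold lower. In this pair 18 miRNAs were higher and 10 lower by 2-fold or more, against 2 and 164 without scaling and 14 and 157 in the deposited table. Entries matching fragments of other RNAs had a median of 0.58, above 99.98% of 10000 random lists matched on expression. The list named GC-rich, set from background knowledge and not checked against sequences, had a median of 0.47, above 99.93%. Yet 2 of its members, miR-494 and miR-513a-5p, were among the lowest 5. The miR-17-92 clusters had a median of -0.15, at the 0.44 percentile. Such percentiles also arose without CPT. Between the DMSO arrays the muscle, neural and liver miRNAs were at 99.83 and those in introns of long host genes at 99.62. Random lists draw their members independently, whereas the fragments of other RNAs had an estimated correlation of 0.78. These percentiles therefore do not show an effect of CPT. miR-34a was at 0.92-fold and miR-21 at 1.18-fold.

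Between CPT 4 h and DMSO 4 h, 131 miRNAs were higher and 191 lower by 2-fold or more among 428, and between the DMSO arrays themselves (20 h against 4 h) 105 were higher and 170 lower among 413. With let-7 scaling these counts became 1 and 248, and 0 and 246. The highest were miR-191 (5.14-fold), miR-142-3p (4.09-fold), miR-1274b (4.01-fold), miR-663 (3.89-fold) and miR-1228 (3.77-fold). The unscaled miR-142-3p signals were 150 and 145, and those of miR-1274b 107200 and 105900. The percentiles used for scaling were 3258 on CPT 4 h and 12920 on DMSO 4 h, so that the unscaled signals alone decide nothing. The size of these folds depends on the scaling, and with let-7 scaling the log2 differences were 0.83 for miR-142-3p and 0.80 for miR-1274b, below 2-fold. The lowest 3 were miR-337-3p at 16.0-fold, miR-619 at 14.6-fold and miR-891a at 13.7-fold lower. The lists that stood out at 20 h did not here. The list named GC-rich had a median of -0.67 (percentile 66.3), the fragments of other RNAs were at the 20.6 percentile and the miR-17-92 clusters at the 58.8 percentile. Other lists did, with the muscle, neural and liver miRNAs at the 99.99 percentile here and at 99.83 between the DMSO arrays. The star strands had a median of -1.66 in this pair (percentile 0.34) and -1.16 between the DMSO arrays (percentile 2.8).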

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

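The 5 fits with the viral covariate, let-7 scaling, both, entries not following the viral signal, or own signals for the floor were chosen after seeing the data. In CPT late against DMSO, 0 miRNAs passed, against 11 with the deposited table, 13 with the viral covariate, 9 with let-7 scaling and the viral covariate, and 30 with let-7 scaling over entries not following the viral signal. Leaving out 1 array gave 0 to 1. The 1 was miR-142-3p, called by limma without CPT early replicate 1 (1 h, adjusted p 0.0436) or replicate 2 (2 h, adjusted p 0.0439). Those arrays enter this comparison only through the shared spread, and the difference stayed at 3.52. These calls therefore do not test the difference itself. In CPT early against DMSO the counts were 0, 3 with the deposited table, 3 with the viral covariate, 1 over entries not following the viral signal and 0 to 71 when leaving out 1 array, 71 without CPT 1 h. In CPT late against CPT early they were 0, 133 with array weights, 4 with the deposited table, 16 with the viral covariate and 8 over entries not following the viral signal. The array weights did not converge and gave CPT 2 h a weight of 6.37 and DMSO 4 h 0.30, and the viral-covariate fit had prior degrees of freedom of 136.5 on 3 residual ones, nearly 1 spread for all miRNAs. A lone array was assumed to vary like the others. Let-7 scaling alone or own signals gave 0.

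List calls in CPT late against DMSO went from 5 to 0 with an estimated correlation, 0 by fry, 1 with quantile normalization, 2 over miRNAs detected on all arrays, 1 with the viral covariate, and 0 to 6 when leaving out 1 array, 0 without DMSO 4 h. In CPT early against DMSO they went from 7 to 0, 0, 2 with quantile normalization, 1 with the viral covariate, and 2 to 8 when leaving out 1 array, 2 without DMSO 4 h. In CPT late against CPT early it gave 0 to 4. In the 20 h pair, 28 miRNAs at 2-fold became 166 without scaling, 171 with the deposited table, 14 with normexp and 16 with quantile normalization. In the 4 h pair 131 higher and 191 lower became 174 and 102 with quantile normalization, 221 and 0 with normexp, 0 and 296 without scaling, 80 and 182 with total gene signal, 18 and 257 with the deposited table, and 1 and 248 with let-7 scaling. The cause was not tested. The median difference of all tested miRNAs in CPT late against DMSO was -0.21, and was 0.09 with quantile normalization, 0.26 with the percentile over all miRNAs, -1.36 without scaling, 0.46 with normexp and -0.57 with let-7 scaling. Of 5624 values of named miRNAs, 5041 kept direction and side of the threshold, 122 came to pass it and 461 changed sign uncalled. The difference of miR-142-3p in CPT late against DMSO ran from 2.36 to 6.59 over 24 alternatives, with adjusted p from 3.65e-12 to 0.998, and passed in 4. Signal over background limits miR-142-3p, which was well above background on 5 arrays.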

Other observations

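The tests in this part were chosen after the results were seen, except that of the genes next to miR-513. Among entries whose signal did not follow that of the viral entries, scaled to let-7, 24 miRNAs were higher and 6 lower in CPT late than in DMSO by limma. Those with the largest differences included miR-1274b (log2 difference 1.21, adjusted p 0.000295), miR-22 (1.13, adjusted p 0.000462), miR-720 (0.83, adjusted p 0.00356), miR-183 (0.82, adjusted p 0.0114) and miR-195 (0.78, adjusted p 0.0217). The minor arms miR-17* (-0.60) and miR-20a* (-0.61) of the miR-17-92 cluster and miR-1246 (-0.64) were lower, each with an adjusted p of 0.0217, while miR-92a of the same cluster was higher (0.46, adjusted p 0.0407). The entries were picked by their slope over the same arrays, which lowers the spread, and among the 413 miRNAs tested as planned miR-22 (2.83-fold) and miR-1274b (2.99-fold) had an adjusted p of 0.746 each. Over all alternatives that p ran from 0.000462 to 1 for miR-22 and from 0.000295 to 1 for miR-1274b.

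Human entries divided along the signal of the viral entries. Of those detected on all arrays, 45.5% had a slope on it under 0.25 and 48.2% a slope over 0.5, with both signals taken relative to let-7. Overall array brightness is argued against, since between DMSO 4 h and DMSO 20 h the viral entries differed from let-7 by 2.71 on the log2 scale. A change in the cells' own miRNAs under CPT is argued against as the whole cause, since the viral entries themselves differed by -2.96 between CPT 4 h and DMSO 4 h, and the DMSO arrays differed too. Non-specific hybridisation remains a candidate explanation, since 19 entries of the chr19 and 14q32 clusters, which are not colon markers, had a median slope of 0.90, with an interquartile range of 0.84.

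The series title's miR-142-3p was higher at 15 and 20 h of CPT than on both DMSO arrays. Signal shared with the viral entries is argued against, since the difference was 3.09 ± 0.36 (SE) with the viral covariate and 2.96 ± 0.36 with let-7 scaling as well. Blood cells in the culture are not excluded. Of miR-223, miR-150 and miR-451, 0 were detected on a late array and none was above its DMSO 4 h signal. Unscaled miR-223 was, however, above its DMSO 20 h signal on both late arrays (264 and 144 against 124). Unscaled miR-150 was above its DMSO 20 h signal at 15 h and below it at 20 h (236 and 85.6 against 164). The percentiles used for scaling were 3228 on CPT 20 h and 6458 on DMSO 20 h, so that the lower signal at 20 h decides nothing. miR-451 was below 0 on both late arrays (-43.4 and -29.7). The miR-223 and miR-150 signals lay near the lowest detected signals, where non-detection decides nothing. An effect of CPT remains open too; p53 was not tested, since no array of these data lacks it. The missing miR-142-5p signal on both late arrays is not accounted for.

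The tested miR-513 entries, miR-513a-5p, miR-513b and miR-513c, were lower on all 5 CPT arrays than on both DMSO arrays. The other arm of the miR-513a hairpin, miR-513a-3p, was detected on 1 array only and was not tested. Signal shared with the viral entries is argued against as the whole cause for miR-513a-5p and miR-513b. CPT 1 h and CPT 15 h had more viral signal than DMSO 20 h, by 0.64 and 0.49. The 4 differences of these entries from DMSO 20 h there, after let-7 scaling, ran from -1.74 to -2.44 (SD 0.30). Their slopes on the viral signal, 0.467 for miR-513a-5p and 0.652 for miR-513b, leave a shared part possible. For miR-513c shared signal stays open, since its -0.90 at 1 h clears the bound of -0.5 by less than the SD of 0.56. These SDs are over entries and times against 1 shared DMSO array, and hold no error between replicates. This comparison, and later its split by entry, replaced one on the viral covariate after its result was seen, where miR-513b, miR-513a-5p and miR-513c were at -2.04 ± 0.39 (SE), -1.75 ± 0.39 and -1.23 ± 0.38 in CPT early and at -2.26 ± 0.35, -1.67 ± 0.35 and -1.78 ± 0.35 in CPT late, about as large as without the covariate or larger, though miR-513a-5p in both and miR-513c in CPT early did not clear -1 by 2 SE. Lower output of the whole cluster could not be examined, since 0 of 9 entries of the neighbouring genes were detected on both DMSO arrays, and so cannot be told apart from a change of these entries alone.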
